A study of Mus musculus with 8 samples.

How the data were processed

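Total RNA was measured in livers of male CD-1 mice after 7 days on a control diet (0 ppm) or on a diet with NaPB (2500 ppm), on one-colour Agilent arrays with 4 arrays per diet. Per the labels, RNA was prepared with Isogen solution and RNeasy columns, Cy3-labelled cRNA was made with the Low Input Quick Amp kit, and the scans were quantified by the authors with Agilent Feature Extraction 10.7. The deposited values are spot intensities on a linear scale, one per feature and array. The 75th percentile over all features was between 0.952 and 0.974 on every array, so the values had been divided by a number close to it before they were deposited; background correction, flags on single spots, the rule of scaling and any floor are not given in the sources used here. Medians were between 0.288 and 0.396, and no value was missing. On NaPB replicate 2 the table holds 3443 distinct values, the most frequent on 228 features, against at least 62756 on the other arrays: its values are whole multiples of 1 step rounded to 3 significant digits, an error of at most 0.0072 log2 units, so ties there are rounded and not filled in. The table held 62976 features, of which 31465 carried 1 gene symbol and 31511 none. Symbols were brought up to date through reference gene tables of the GRCm38.p6 mouse assembly, used for names alone, and 3282 features changed symbol. This left 20738 genes, 6171 of them with more than 1 feature.

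The values were taken as log2 of the deposited intensity, with no pseudocount, no further scaling and no filter on dim genes. Each gene was represented by the feature with the highest mean over the 8 arrays. A linear model with diet as its only term was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with default settings), two-sided, with Benjamini-Hochberg adjustment over all genes tested. Genes were called at an adjusted p below 0.05. The ± values are limma standard errors on the log2 scale, with 4 arrays per diet. A value up to 2 times the lowest value of its array was counted as at the floor, and the fold of a gene with all 4 control arrays at the floor is given as a lower bound; 1481 genes had all control arrays at the floor, 790 of them all 8 arrays. The number of arrays limits the precision.

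The 38 gene lists, the rule for naming genes, the tests and most alternatives were chosen before the data were examined. Each list was tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, fry, which tests whether the members move one way and compares them with no other genes, and the number of members passing when p was adjusted over the list alone. None of the camera calls held with an estimated correlation. The genes named are the 10 with the largest and the 10 with the smallest log2 fold change among called genes whose diets did not overlap, leaving out uncharacterised symbols; the 4 members with the smallest p of each list that camera called or that had at least 5 called members, and the member with the smallest p of each other list; and 13 index genes. Other genes are named where a count of 5 or fewer asks for it or after their values were seen.

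The model was tested on simulated data with the spread of these arrays (10 draws with 200 changed genes each). It recovered 8% of genes changed by 1 log2 unit, 60.8% at 2, 87.4% at 3 and 95.2% at 4, with 3.72% of the calls false. A list shifted by 1 log2 unit was called in every draw. The simulated genes were independent of each other and no simulated array stood apart. In the real data the estimated correlation within a list reached 0.95. The share of false calls and the list result therefore hold for the simulated setting alone. Alternatives were quantile normalization, shifts of each array to the same 75th percentile or median, filters on dim genes at the first quartile or the median of mean intensity, the mean of all features of a gene, all features tested singly, pseudocounts of 1 and of the 5th percentile of the table, a variance trend with robust estimation, array weights, the replicate number as a block, a test of each gene by itself with unequal variances, thresholds of 0.01 and 0.1, and leaving out each array in turn. The 35 splits of the 8 arrays into 4 and 4 were also fitted. Leaving out control replicate 1 with NaPB replicate 4, and quantile normalization without NaPB replicate 4, were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.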

Results

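Liver RNA of male CD-1 mice, an outbred stock, was measured on 8 one-colour Agilent arrays. Of these, 4 came from livers taken after 7 days on a control diet (0 ppm) and 4 from livers taken after 7 days on a diet with 2500 ppm NaPB, the sodium salt of phenobarbital, a barbiturate that activates the nuclear receptor CAR in hepatocytes. The comparison asks which liver transcripts differed between the diets. According to the title of the series, these mouse livers belong to work on liver growth caused by phenobarbital in mice that carry human hepatocytes; those other livers were not analysed here. Each array held 62976 features (spots), and 20738 named genes were tested, each through its brightest feature. The number of arrays limits the precision. The titles of the NaPB samples carry numbers that are not consecutive and could be those of animals, but no label says that the arrays of a diet came from separate animals, so the p-values measure only the spread between these samples, which need not be the spread between mice. Pearson correlations between arrays, across the log2 values of genes, which are not independent replicates, ran from 0.914 to 0.965 within the control diet, from 0.914 to 0.968 within the NaPB diet and from 0.871 to 0.954 between diets. A pair of arrays stood apart, control replicate 1 and NaPB replicate 4, at the ends of the first principal component (33.5% of the variance). Their median correlations with the other arrays were 0.914 and 0.931, against 0.933 to 0.950 for the rest, and they had the lowest array weights (0.308 and 0.313). The 99th percentile of NaPB replicate 4 was 62.3 times its 75th percentile, against 107 to 125 on the other NaPB arrays and 65.8 to 124 on the control arrays.

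On the NaPB diet, transcripts of some enzymes that oxidize or conjugate foreign compounds rose, among them 10 of 19 genes in a list of P450 genes known to respond to the receptors CAR and PXR and 8 of 22 glutathione S-transferase genes. Cyp2b10, the P450 classically induced by phenobarbital in mouse liver, was 114-fold higher. The glutathione transferase genes Gstm3 and Gsta1 were 44.2-fold and 32.3-fold higher. The oestrogen sulfotransferase gene Sult1e1, at the floor of the arrays in the controls, was at least 31.7-fold higher. In the other direction, Hsd3b5, a male-typical steroid dehydrogenase gene of mouse liver, was 78.7-fold lower and Serpina4-ps1, a serpin pseudogene, was 53.9-fold lower. Hsd3b5 was at the floor on 1 NaPB array, and 40.8-fold lower without NaPB replicate 4. In all, limma called 209 genes at an adjusted p below 0.05, 81 higher and 128 lower on the NaPB diet, each by more than 2-fold, with a smallest absolute log2 fold change of 1.26; 2095 genes had an unadjusted p below 0.05. The values of the diets did not overlap for 1459 genes, 7.04% of those tested, where chance gives 2.86%. All 209 were among the genes without overlap. The count was 365 genes (211 higher, 154 lower) without NaPB replicate 4. It was 88, 107 and 94 without NaPB replicates 1, 2 and 3, and 119, 91 and 99 without control replicates 2, 3 and 4.

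**Figure D1:**
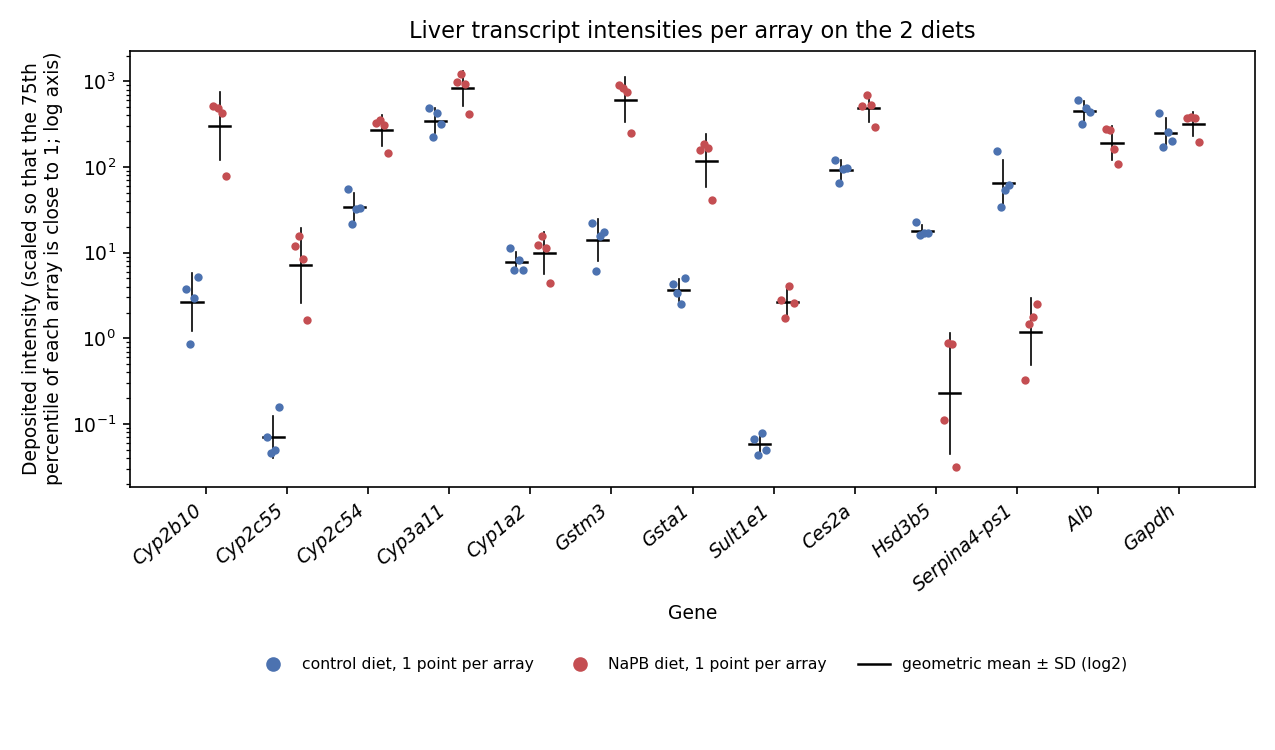
Deposited intensity (log axis) of 13 genes on each of the 8 arrays, blue for the control diet and red for the NaPB diet, with the geometric mean and SD on the log2 scale as black lines. Cyp2b10 lay between 0.863 and 5.22 on the control arrays and between 77.7 and 521 on the NaPB arrays, while Gapdh overlapped between the diets.

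The P450 genes known to respond to CAR or to its relative PXR formed the list with the clearest difference; it also holds Por, the P450 reductase gene, and Alas1, of heme synthesis. Of 19 measured members, 10 rose, none fell and 9 did not pass the test; adjusted over the list alone, 12 rose. The median log2 fold change was 2.50. Cyp2b10 had a geometric mean intensity of 2.66 on the control diet (log2 SD 1.13, n = 4) and 304 on the NaPB diet (log2 SD 1.32, n = 4), a log2 fold change of 6.84 ± 0.69 (SE; limma adjusted p = 0.0018). Cyp2c55 differed by 6.65 ± 0.67 on the log2 scale, with 3 control arrays at the floor, and Cyp2c54 by 3.00 ± 0.38, with limma adjusted p of 0.0018 and 0.00593. Without NaPB replicate 4 the log2 fold changes of Cyp2b10 and Cyp2c55 were 7.49 and 7.36. Cyp3a44 was at the floor on all control arrays and at least 8.28-fold higher. A pair of members abundant in control liver did not pass over all genes: Cyp3a11 had a log2 fold change of 1.24 ± 0.39 (limma adjusted p = 0.237), and Cyp2c29 had a log2 fold change of 1.07 ± 0.45 (limma adjusted p = 0.436), with its 10 features between 1.06 and 1.46. Without NaPB replicate 4, Cyp3a11 passed (limma adjusted p = 0.0475). The members' mean lay 2.87 to 3.27 log2 units above the control mean on NaPB replicates 1 to 3 and 1.43 above it on NaPB replicate 4. The list was called by camera (adjusted p = 2.58e-24), and by fry (adjusted p = 0.0164), but not with an estimated correlation (adjusted p = 0.22).

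Among 30 other P450 genes, 1 rose and none fell; adjusted over the list alone, 1 rose and 3 fell, and the list was not called (camera adjusted p = 0.57, median log2 −0.16). Adjusted over the list alone, 4 rose without NaPB replicate 4, 5 fell without NaPB replicate 2 and 1 fell without control replicates 1, 3 or 4 or NaPB replicate 1. The gene that rose was Cyp2c39, 7.33-fold higher. Outside these genes, Cyp1a2, a marker of the Ah receptor that stands in the CAR and PXR list, had a log2 fold change of 0.36 ± 0.40. Cyp4a10, a marker of PPARα from the list of PPARα targets, had one of −0.79 ± 0.75. Neither passed. Nr1i3, which encodes CAR itself, had a log2 fold change of −0.21 ± 0.33.

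Some genes of conjugating enzymes rose. Of 22 glutathione S-transferase genes, 8 rose and none fell (9 and none adjusted over the list alone; median log2 0.39, which was 0.69 without NaPB replicate 4 and 0.26 without NaPB replicate 1). Gstm3 had a log2 fold change of 5.47 ± 0.50, Gsta1 of 5.01 ± 0.48, Gsta2 of 4.00 ± 0.40 and Gstm1 of 2.95 ± 0.36, with limma adjusted p between 0.00152 and 0.00485; both features of Gstm3 (3.66 and 5.47) and of Gstm1 (2.71 and 2.95) were higher. Of 26 glucuronosyltransferase and sulfotransferase genes, a list that also holds 4 genes supplying their cosubstrates (Ugdh, Ugp2, Papss1 and Papss2), 5 rose and none fell, all 5 being sulfotransferase genes; adjusted over the list alone, 7 rose and 1 fell, and the median log2 was 0.55. In the fit without NaPB replicate 4, 8 rose and none fell, 17 rose and 2 fell adjusted over the list alone, and the median was 1.01; without NaPB replicate 2 the median was 0.27, and without control replicate 3 or NaPB replicate 3 none fell adjusted over the list alone. Sult2a1 was at least 36.9-fold and Sult2a2 at least 15.4-fold higher, both at the floor on every control array, and Sult1d1 was 5.05-fold higher (limma adjusted p = 0.0127). Sult1d1 was not called without NaPB replicate 1 (limma adjusted p = 0.0508). Without NaPB replicate 2 the lower bounds for Sult2a1 and Sult2a2 were 57.1-fold and 23.2-fold. Camera called both lists (adjusted p = 8.56e-08 for the transferases of glutathione, 6.76e-06 for the others), and neither with an estimated correlation (adjusted p = 0.755 for both). The mean of the glutathione S-transferase list lay 1.57 to 1.73 log2 units above the control mean on NaPB replicates 1 to 3 and 0.30 above it on NaPB replicate 4. For the glucuronosyltransferase and sulfotransferase list these means were 1.46 to 1.70 and −0.03.

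Of 34 genes of other drug-metabolizing enzymes, 3 rose and none fell; adjusted over the list alone, 7 rose and 4 fell. Leaving out NaPB replicate 4 gave 9 higher and 2 lower, and 18 and 4 adjusted over the list alone. Without control replicates 1, 3 or 4 or NaPB replicate 1, 2 fell adjusted over the list alone. The carboxylesterase genes Ces2c and Ces2a were 5.72-fold and 5.21-fold higher and the aldehyde dehydrogenase gene Aldh1a7 was 4.29-fold higher, whereas Ces3b had a log2 fold change of −2.13 ± 0.44 that did not pass (limma adjusted p = 0.0536) except without NaPB replicate 2 or NaPB replicate 4 (0.0415 and 0.0379). Aldh1a7 was called only with all arrays and without control replicate 1 or NaPB replicate 4; leaving out control replicates 2, 3 or 4 or NaPB replicates 1, 2 or 3 gave adjusted p of 0.0923, 0.0984, 0.0945, 0.119, 0.0951 and 0.104. The list was called higher (camera adjusted p = 0.00356, median log2 0.62, which was 0.93 without NaPB replicate 4 and 0.39 without NaPB replicate 2), not with an estimated correlation (adjusted p = 0.889), and not without NaPB replicate 2 (camera adjusted p = 0.0777). Among 19 targets of Nrf2, the regulator of antioxidant genes, 1 rose (2 adjusted over the list alone) and the median log2 was 0.44. Of these targets 3 rose without NaPB replicate 4 (10 adjusted over the list alone), with a median of 0.91, and without NaPB replicates 1 or 2 it was 0.28 and 0.25. The gene that rose with all arrays was Abcc4, an efflux transporter gene, 6.29-fold higher; of the 8 fits that left out 1 array, only the one without NaPB replicate 4 called it, and the others gave adjusted p from 0.0648 (without control replicate 1) to 0.136 (without NaPB replicate 1). Cbr3 (log2 2.64 ± 0.59), Fth1 (0.86 ± 0.34) and Gsta4 (0.70 ± 0.28, all 10 features above 0) did not pass, Cbr3 doing so without NaPB replicate 4 (limma adjusted p = 0.0036). The Nrf2 list was called (camera adjusted p = 0.0293) but not with an estimated correlation (adjusted p = 0.889), nor without control replicate 2 (adjusted p = 0.157) or NaPB replicates 1, 2 or 3 (0.187, 0.131 and 0.0936). On NaPB replicate 4 the Nrf2 targets lay at −0.81 log2 units from the control mean, against 0.78 to 1.02 on the other NaPB arrays. The other drug-metabolizing genes lay at −0.70 against 0.66 to 0.95. Of 20 xenobiotic and bile transporter genes, 1 rose, Abcc4, and 1 fell, Slc22a7, an organic anion transporter gene, which was 4.45-fold lower. Slc22a7 was not called without control replicates 1, 2 or 3 (adjusted p = 0.0513, 0.0513 and 0.0773) or NaPB replicates 1 or 3 (0.0725 and 0.0537). Abcc2 and Abcc3 rose as well without NaPB replicate 4. Adjusted over the list alone, 3 rose and 2 fell (with 1 array left out, 1 without NaPB replicate 1 to 4 without NaPB replicate 4 rose, and 1 without control replicates 1, 3 or 4 or NaPB replicate 1 to 3 without control replicate 2 fell), and the list was not called (camera adjusted p = 0.57, median log2 −0.29).

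Among genes with sex-biased expression in mouse liver, 8 of 15 female-biased genes rose and 1 of 15 male-biased genes fell. Of the 15 measured female-biased genes none fell (adjusted over the list alone, 10 rose and none fell; median log2 2.05; without control replicate 1, 5 rose over all genes), and camera called the list (adjusted p = 1.95e-14), but not with an estimated correlation (adjusted p = 0.134). The 4 members with the smallest p were Cyp3a44, Sult2a1, Prom1 and Cyp2b9. Cyp2b9 was 24.8-fold higher (log2 4.63 ± 0.65, limma adjusted p = 0.00849). Prom1, which encodes prominin-1, was 45-fold higher by its brightest feature, with 2 control arrays at the floor, and its other feature gave a log2 fold change of 0.76; without NaPB replicate 4 the log2 fold changes of Cyp2b9 and Prom1 were 5.37 and 6.32. Of the 15 genes, 5 also stand in the CAR and PXR list. Of 15 male-biased genes, 1 fell, Hsd3b5, and none rose; adjusted over the list alone, 6 fell, against 3 without NaPB replicate 4 and 1 without control replicates 1 or 3 or NaPB replicate 1. The list was called lower (camera adjusted p = 5.26e-05, median log2 −0.40, which was −0.23 and −0.26 without NaPB replicate 4 or control replicate 1 and −0.69, −0.62 and −0.61 without control replicate 2 or NaPB replicates 2 or 3), but not with an estimated correlation (adjusted p = 0.755). Hsd3b5 had a log2 fold change of −6.30 ± 0.91 (limma adjusted p = 0.0101), which was −6.95, −6.94 and −5.35 without NaPB replicates 2, 3 and 4. Cyp7b1 (−1.74 ± 0.46), Elovl3 (−2.22 ± 0.68) and Nox4 (−1.39 ± 0.43) did not pass over all genes. By fry the adjusted p was 0.00849 for the female-biased and 0.442 for the male-biased list. The female-biased list lay 2.58 to 3.31 log2 units above the control mean on NaPB replicates 1 to 3, and NaPB replicate 4 differed from the mean of those arrays by a median of −1.32 over its members. The male-biased list lay at −1.25, −0.42, −0.55 and −2.04 log2 units on NaPB replicates 1 to 4.

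Of the 38 lists, 3 had a smaller camera p with the real diets than with every other of the 35 splits of the arrays into 4 and 4: the CAR and PXR target P450 genes, the female-biased genes and the Kupffer cell and macrophage markers. Another split was first in this way for 5 lists, and for each of the other called lists at least 1 other split gave a p as small.

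**Figure D2:**
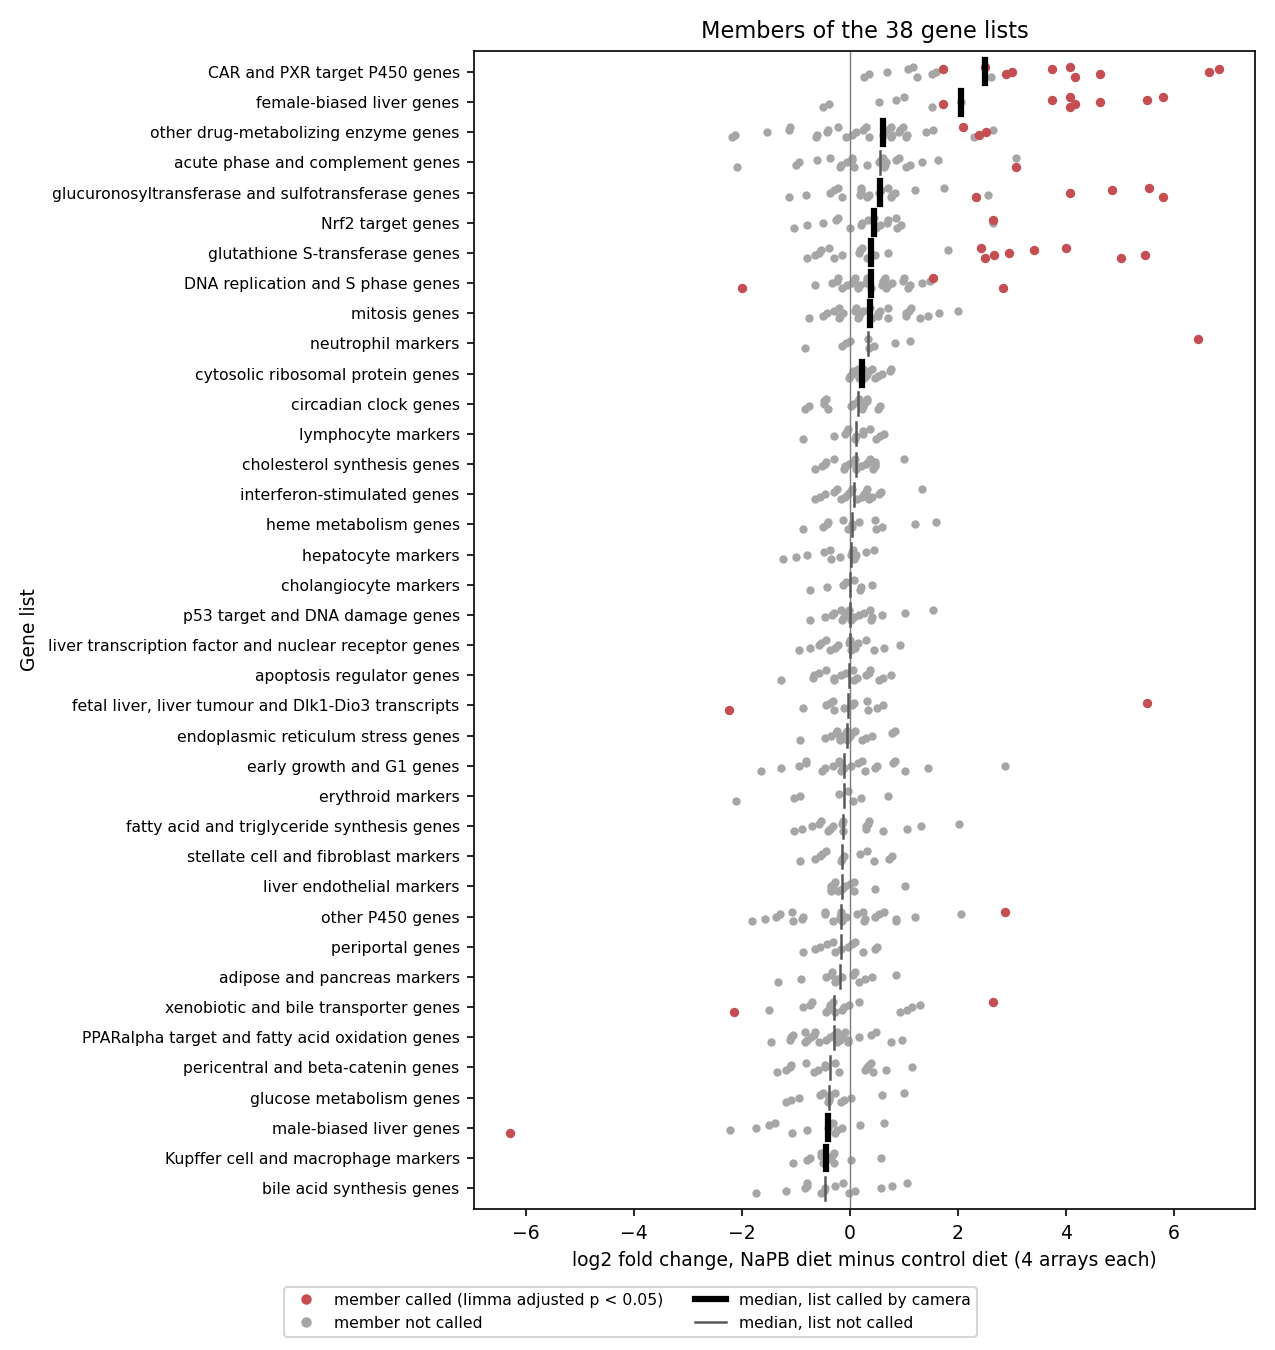
log2 fold change (NaPB diet minus control diet, 4 arrays each) of every measured member of the 38 gene lists, red where limma called the gene and grey where it did not, with the list median as a bar that is thick where camera called the list. The CAR and PXR target P450 genes and the female-biased genes have medians of 2.50 and 2.05, and the other lists lie between −0.46 and 0.62.

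Among cell cycle genes, the lists of S phase and of mitosis were called higher by camera, in neither case with an estimated correlation, and few single genes passed. Of 31 DNA replication and S phase genes, 2 rose, 1 fell and 24 had a log2 fold change above 0 (median 0.39; the same counts passed adjusted over the list alone). Leaving out NaPB replicate 4, 3 rose and 1 fell, 6 rose and 1 fell adjusted over the list alone, and the median was 0.65; without control replicate 1 it was 0.26. Rrm2, a subunit gene of ribonucleotide reductase, was 7.11-fold higher, with 1 control array at the floor, and Chaf1b, a chromatin assembly factor gene, was 2.91-fold higher by its brighter feature and higher by both. Mcm10, a replication initiation gene, was 3.98-fold lower. Of the 8 fits with 1 array left out, only the one without NaPB replicate 4 called these 3 genes; the others gave adjusted p of 0.0648 to 0.0964 for Rrm2, 0.0548 to 0.156 for Chaf1b and 0.0724 to 0.144 for Mcm10. Cdt1 had a log2 fold change of 1.47 ± 0.50 that did not pass. Of 29 mitosis genes none passed over all genes or adjusted over the list alone, 21 lay above 0 and the median log2 was 0.37, which was 0.12 without control replicate 1; Cdc20 (2.00 ± 0.62), Plk1 (1.64 ± 0.63), Ube2c (1.04 ± 0.30) and Tpx2 (0.71 ± 0.27) had the smallest p, and Ube2c passed without NaPB replicate 4 (limma adjusted p = 0.0456). Adjusted over the list alone, 2 rose without that array and 1 without NaPB replicate 2. With 1 array left out, the log2 fold change of Cdc20 ran from 1.36 (without NaPB replicate 1) to 2.51 (without NaPB replicate 2). That of Plk1 ran from 1.07 (without NaPB replicate 1) to 2.26 (without NaPB replicate 4). Camera called the S phase list (adjusted p = 0.00179) and the mitosis list (adjusted p = 0.00703), with no call under an estimated correlation (adjusted p = 0.755 for both). The mitosis call was lost without NaPB replicate 4 (camera adjusted p = 0.0685) and without control replicate 1 (adjusted p = 0.126). S phase members averaged 0.97, 0.46, 0.48 and −0.08 log2 units from the control mean on NaPB replicates 1 to 4, and mitosis members 0.95, −0.05, 0.53 and 0.33. Mki67, the proliferation marker Ki-67, had a log2 fold change of 0.52 ± 0.48 and was not called.

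Early growth and G1 genes were not called as a list (23 measured, none passed over all genes, 1 higher adjusted over the list alone; median log2 −0.10, mean 0.05; camera adjusted p = 0.895). Gadd45b, a stress-response gene known to be induced through CAR, lay between 1.29 and 2.10 on the control arrays and at 19.9, 26.8, 14.3 and 2.04 on NaPB replicates 1 to 4 (limma adjusted p = 0.0915). Without NaPB replicate 4 it passed with a log2 fold change of 3.68 (limma adjusted p = 0.00109), as did Jun, and 3 members rose and 1 fell adjusted over the list alone. Without control replicate 1, 1 rose and 1 fell in this way, and none did in the other fits with 1 array left out. Ccnd1, the cyclin D1 gene, was at the floor on 2 control arrays and 1 NaPB array and had a log2 fold change of 1.03 ± 0.79. Of 20 p53 target and DNA damage genes none passed (1 higher adjusted over the list alone; median log2 0.00, camera adjusted p = 0.57); that member was Ephx1, also an epoxide hydrolase of drug metabolism (log2 1.54 ± 0.33, limma adjusted p = 0.0636, and 0.0288 without NaPB replicate 4), 2 members rose over the list alone without control replicate 2 and none without NaPB replicates 2 or 3, and Cdkn1a, the p21 gene, had a log2 fold change of 0.08 ± 0.88. Of 18 apoptosis regulators none passed by either adjustment (median log2 −0.01, camera adjusted p = 0.623), and Cflar had the smallest p (−0.67 ± 0.27). In the list of fetal liver, liver tumour and Dlk1-Dio3 transcripts (14 measured), Prom1 rose and Igf2 fell by either adjustment, Igf2 being called over all genes only with all arrays and without control replicate 3 or NaPB replicate 4, the list median was −0.03, its mean was 0.20 and the list was not called (camera adjusted p = 0.959).

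Of the lists of intermediary metabolism none was called and no member passed over all genes. The camera adjusted p was 0.083 for PPARα targets and fatty acid oxidation (27 genes, 22 below 0, median log2 −0.30), for bile acid synthesis (15 genes, 11 below 0, median −0.46) and for glucose metabolism (15 genes, 12 below 0, median −0.38); adjusted over the list alone no member passed. With 1 array left out, 1 fell in this way among PPARα targets (without control replicate 2 or NaPB replicate 1), bile acid synthesis (without NaPB replicates 2, 3 or 4) and glucose metabolism (without NaPB replicate 4). Acot1 (−1.46 ± 0.48), Cyp7b1 and Irs2 (−1.10 ± 0.31) had the smallest p in these lists. PPARα targets were called lower without control replicate 2 (adjusted p = 0.00506) or NaPB replicates 1 or 2 (0.00922 and 0.0399). Bile acid synthesis was called lower without control replicate 2 (0.0405) or NaPB replicates 1, 2 or 3 (0.0399, 0.0426 and 0.0496). Glucose metabolism was called lower without control replicates 2 or 4 (0.016 and 0.0461) or NaPB replicate 2 (0.0426). Quantile normalization also called the 3 lists lower (adjusted p = 0.0301, 0.00456 and 0.038). Fatty acid and triglyceride synthesis (19 genes, median −0.13, mean 0.05, camera adjusted p = 0.889) and cholesterol synthesis (20 genes, median 0.11, camera adjusted p = 0.646) were called higher without NaPB replicate 4 (adjusted p = 0.00374 and 9.11e-06) and with array weights (0.0353 and 0.000904). Their medians without NaPB replicate 4 were 0.28 and 0.62, and 3 and 6 members rose adjusted over the list alone. With quantile normalization as well, cholesterol synthesis was still called higher (camera adjusted p = 0.000126), while fatty acid and triglyceride synthesis was not called. Over all genes, the members of the metabolic lists that passed without that array were Elovl6, Thrsp, Akr1d1, Alas1 and Cyb5a, all higher. Elovl6, a fatty acid elongase gene, was at 14.3, 10.9, 10.4 and 0.973 on NaPB replicates 1 to 4 against at most 1.80 on the control arrays, and passed without that array (limma adjusted p = 0.00148). Sqle, of sterol synthesis, was at 14.4, 13.4, 13.1 and 3.29 against 3.13 to 6.91. Heme metabolism (14 genes, median 0.04, camera adjusted p = 0.623; Cyb5a 2.29-fold higher, limma adjusted p = 0.228) and endoplasmic reticulum stress (20 genes, median −0.05, adjusted p = 0.889; Sdf2l1 −0.93 ± 0.29) were not called. Neither were pericentral and beta-catenin genes (18 genes, median −0.37, adjusted p = 0.113; Slc1a2 −1.36 ± 0.35, the only one to pass adjusted over the list alone, where none fell without control replicates 1, 3 or 4 or NaPB replicates 2, 3 or 4, and called over all genes without control replicate 2, adjusted p = 0.0483) and periportal genes (13 genes, median −0.17, adjusted p = 0.49; Hal −0.65 ± 0.26). Circadian clock genes (17 genes, median 0.15, mean −0.03, adjusted p = 0.959; Nfil3 −0.44 ± 0.24) and liver transcription factors and nuclear receptors (18 genes, median −0.01, adjusted p = 0.57; Ppara −0.94 ± 0.30) were not called. Cyb5a passed without NaPB replicate 4 (adjusted p = 0.0288), and the pericentral list was called lower without control replicate 2 or NaPB replicate 1 (adjusted p = 0.0494 and 0.0367). Adjusted over the list alone, 1 pericentral member rose without NaPB replicate 4. Cytosolic ribosomal protein genes were called higher (25 genes, 23 above 0, median 0.22, camera adjusted p = 0.0131) with no single member past the test by either adjustment; Rpl4 (0.77 ± 0.30), Rpl32 (0.74 ± 0.33), Rpl27 (0.59 ± 0.37) and Rpl13a (0.52 ± 0.33) had the smallest p. That call was absent with an estimated correlation (adjusted p = 0.889) and without control replicates 2 or 4 (0.277 and 0.0764) or NaPB replicates 2 or 3 (0.274 and 0.071). The median was 0.50 and 0.37 without NaPB replicate 4 or control replicate 1, and 0.09 and 0.07 without control replicate 2 or NaPB replicate 2. The members' mean was −0.50 log2 units from the control mean on NaPB replicate 4 and 0.42 to 0.73 on the other NaPB arrays. Among the controls it was highest on replicate 1 (0.38) and lowest on replicate 2 (−0.44). These had the largest and smallest control ratios of 99th to 75th percentile (124 and 65.8). The members' median gap between NaPB replicate 4 and the other NaPB arrays was −0.92, and −0.09 after quantile normalization. The list was still called higher by camera after quantile normalization, which argues against the range of the arrays as the whole cause of the call. A part played by that range, or by another difference between arrays that these genes share, is not separated from diet.

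Of the lists of cell type markers, the macrophage list alone was called. All but 2 of the 13 Kupffer cell and macrophage markers lay below 0, none passed over all genes and 1 did adjusted over the list alone (median log2 −0.44), where none did without control replicate 3 or NaPB replicates 1 or 3. The complement genes C1qa (−1.05 ± 0.24), C1qc (−0.74 ± 0.31) and C1qb (−0.53 ± 0.24) and Adgre1, the F4/80 gene (−0.79 ± 0.33), had the smallest p. The list was called lower by camera (adjusted p = 0.00137) and by fry (adjusted p = 0.00849), and in all 8 fits with 1 array left out, but not with an estimated correlation (adjusted p = 0.266). Its mean was −0.47, −0.23, −0.44 and −0.50 log2 units from the control mean on NaPB replicates 1 to 4. Hepatocyte markers (15 genes, median 0.01, mean −0.22, camera adjusted p = 0.241), cholangiocyte markers (8 genes, median 0.00, mean −0.06, adjusted p = 0.686), stellate cell and fibroblast markers (13 genes, median −0.14, adjusted p = 0.623) and endothelial markers (13 genes, median −0.15, adjusted p = 0.699) were not called. The same held for lymphocyte markers (13 genes, median 0.11, adjusted p = 0.623), erythroid markers (8 genes, median −0.12, adjusted p = 0.218), adipose and pancreas markers (14 genes, median −0.19, adjusted p = 0.457) and interferon-stimulated genes (20 genes, median 0.08, adjusted p = 0.623). No member of these lists passed over all genes. Adjusted over the list alone, 2 hepatocyte markers (Alb, 2.36-fold, and Apoa1, 2-fold) and 2 erythroid markers (Alas2 and Slc4a1) were lower. No hepatocyte marker was in any fit with 1 array left out but that without control replicate 2, and no erythroid marker without control replicates 2, 3 or 4 or NaPB replicates 1 or 3. The hepatocyte list was called lower without control replicate 2 (adjusted p = 0.0467), and Alas2 passed without control replicate 1 (adjusted p = 0.0137). The smallest p in the remaining lists belonged to Sctr (−0.73 ± 0.26), Reln (−0.93 ± 0.29), Lyve1 (1.01 ± 0.38), Gzma (−0.87 ± 0.31), Alas2 (−2.11 ± 0.61), Cel (−0.90 ± 0.26) and Cxcl10 (1.34 ± 0.52). Gapdh (0.36 ± 0.36) and Actb (−0.26 ± 0.34) were not called. Among 10 neutrophil markers, S100a8 alone passed, by either adjustment (log2 6.43 ± 1.04, limma adjusted p = 0.0176; 46.3, 126, 71.0 and 2.02 on NaPB replicates 1 to 4 against at most 0.464 in the controls). It was not called without control replicates 1, 2 or 3 (adjusted p = 0.0506, 0.0556 and 0.0561) or NaPB replicates 1 or 3 (0.0654 and 0.0544), and its log2 fold change was 5.75 without NaPB replicate 2 and 7.74 without NaPB replicate 4. Its usual partner S100a9 was at 2.76, 1.19, 1.41 and 6.63 against 1.06 to 2.00. The neutrophil list was not called (median log2 0.34, camera adjusted p = 0.0954).

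The acute phase and complement list (26 genes) had 1 member past the test, Orm3, an orosomucoid gene, 8.46-fold higher on the NaPB diet and called in all 8 fits with 1 array left out; adjusted over the list alone 2 rose and 1 fell. Without control replicates 1, 2 or 4, 1 rose and none fell in this way. Leaving out NaPB replicate 4, Lcn2 also rose and Itih3 fell over all genes, and 3 fell adjusted over the list alone. The list was not called (median log2 0.56, camera adjusted p = 0.0959) but was called higher without control replicate 3 (0.0188) or NaPB replicates 1, 2 or 3 (0.00922, 0.0426 and 0.0121). Without NaPB replicate 4 its direction was down (median log2 −0.28, adjusted p = 0.342), and with quantile normalization as well it was called lower (adjusted p = 0.0107). The list's mean lay between −0.15 and 0.03 log2 units from the control mean on NaPB replicates 1 to 3 and 1.96 above it on NaPB replicate 4. The serum amyloid genes Saa1 and Saa2, chosen after their values were seen, were at 1713 and 1272 on NaPB replicate 4 and at most at 46.3 and 27.9 on the other 7 arrays. Lcn2 was at 216 there and at 18.5, 12.7 and 8.40 on NaPB replicates 1 to 3, against 2.15 to 5.91 on the control arrays.

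**Figure D3:**
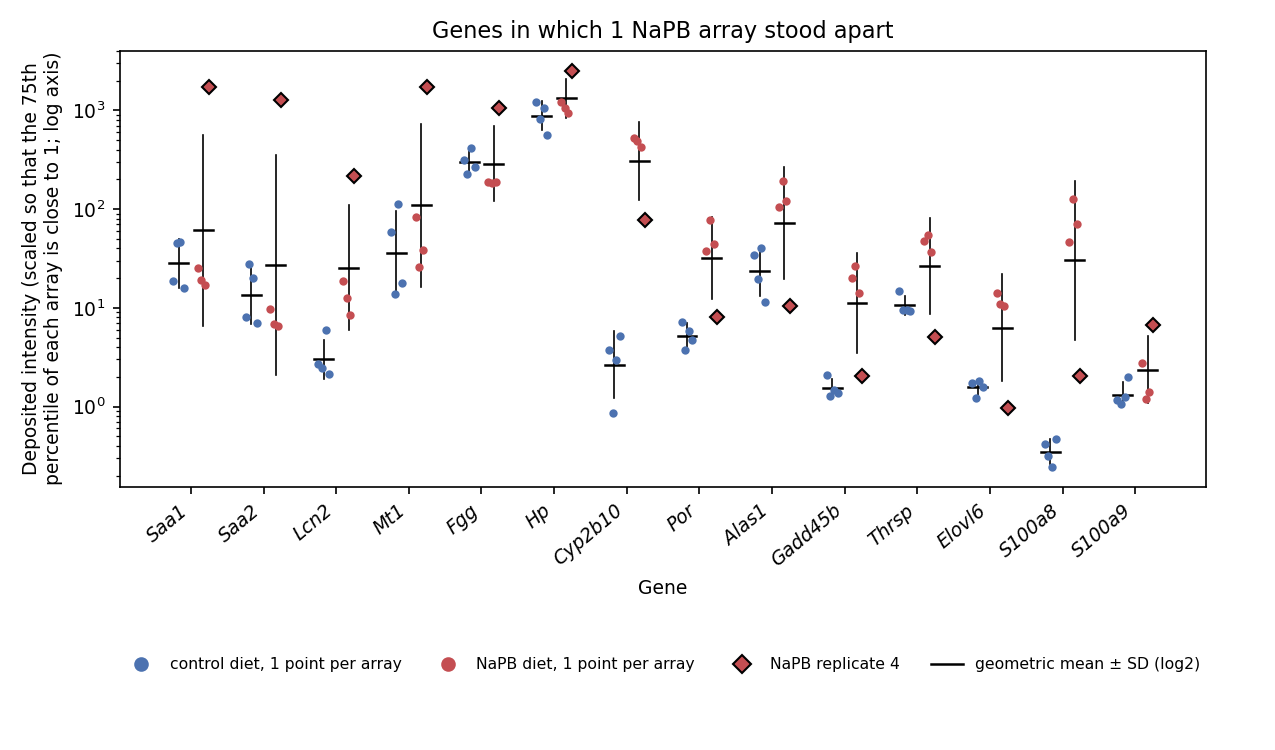
Deposited intensity (log axis) of 14 genes, 8 of them acute phase or neutrophil genes and 6 genes of drug response, growth or lipid synthesis, on each array, with NaPB replicate 4 as a diamond and the geometric mean and SD on the log2 scale as black lines. NaPB replicate 4 had Saa1 at 1713 and Cyp2b10 at 77.7, where the other NaPB arrays had 16.9 to 25.4 and 430 to 521.

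Of the 128 genes called lower, 12 had a mean log2 intensity above 2. After Hsd3b5 and Serpina4-ps1 the largest falls were those of Pate14 (log2 −4.55 ± 0.62), Sp7, an osteoblast transcription factor gene (−3.96 ± 0.35), the olfactory receptor gene Olfr190 (−3.63 ± 0.62), Cbfa2t3 (−3.20 ± 0.33), Cdk15 (−3.11 ± 0.41), Susd4 (−2.94 ± 0.45), Spats2l (−2.91 ± 0.28) and Zfp882 (−2.85 ± 0.48), with limma adjusted p between 0.00149 and 0.0238. On the NaPB diet Sp7 was at the floor on 3 arrays, Pate14 and Olfr190 on 2 each, and Cdk15 and Hsd3b5 on 1 each, so the sizes of these falls depend on values not above background. The other features of Cbfa2t3 and Olfr190 did not share the fall, with log2 fold changes up to 0.64 and 0.05; of the 3 features of Zfp882, 2 were lower and 1 was at 0.93. Olfr190 was not called without control replicate 2 (adjusted p = 0.0744) or NaPB replicates 1, 2 or 3 (0.0866, 0.0676 and 0.0523), nor Zfp882 without control replicate 2 (0.0685) or NaPB replicates 1 or 3 (0.077 and 0.0716). The log2 fold change of Serpina4-ps1 was −5.12 without NaPB replicate 1. Beyond the drug-metabolizing genes, Meig1 (log2 5.71 ± 0.51, with 5.49 at its other feature) and Mical1 (4.99 ± 0.62, and 5.66 without NaPB replicate 4) were among the largest rises, with 2 control arrays at the floor for Meig1 and 1 for Mical1. Of the 209 called genes, 150 rested on a single feature. Among 19 called-higher genes with more features, 17 of their 23 other features were also higher, with a median log2 fold change of 2.53, and among 40 such called-lower genes 48 of 80 other features were also lower, with a median of −0.15. Olfr1307, Olfr74 and Rag2, with 10, 10 and 11 features, weigh heavily in this last count. Of their features 7, 5 and 5 were lower, the brightest included. Of 386 genes with at least 8 features each (3995 features), 51 features in 28 genes differed by diet from the mean of their own gene (limma adjusted p below 0.05), 1.28% of them, against 1.01% of genes called in the main comparison. Of the 51, 4 had a mean intensity above 1, as did 1019 of the 3995 features, so these differences were mostly among dim features.

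**Figure D4:**
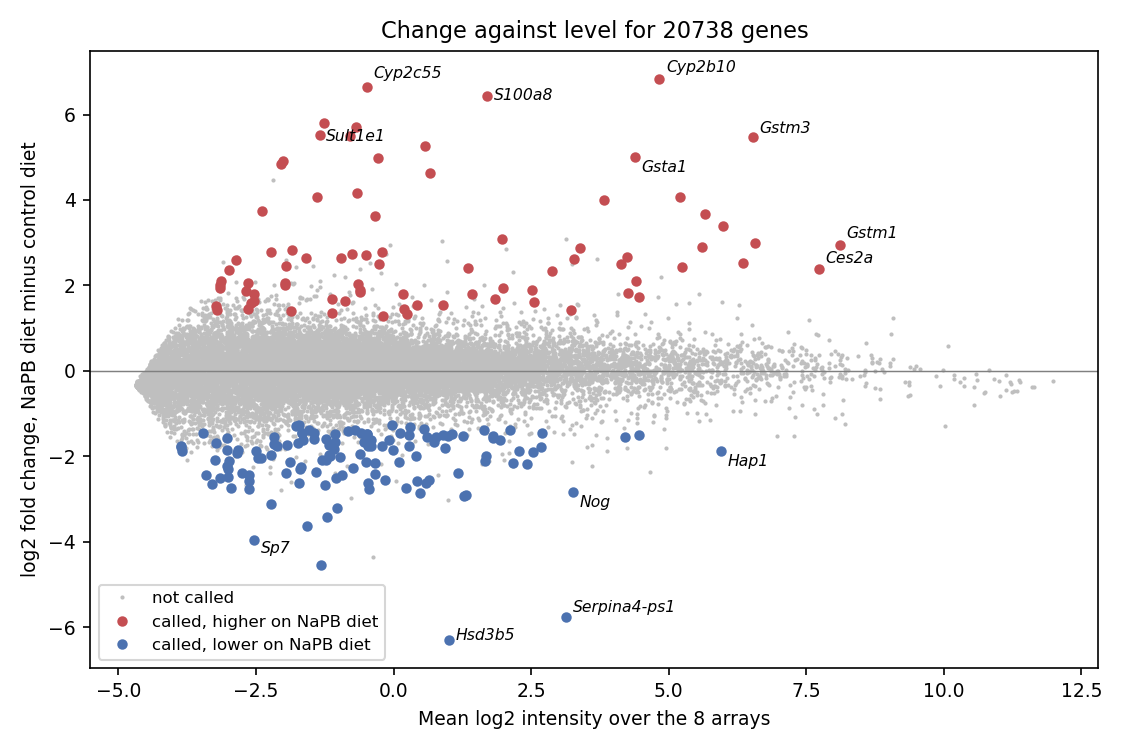
log2 fold change (NaPB diet minus control diet) against mean log2 intensity over the 8 arrays for 20738 genes, grey where not called, red where called higher and blue where called lower. Above a mean log2 intensity of 2, 24 called genes were higher and 12 lower, and the remaining calls lie among dimmer genes.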

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

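The tests of explanations and the splits of the arrays below were all chosen or run after the results were seen. Within a diet, the array farthest from the others was compared with the range of its group by Dixon's ratio at its 95% critical value for 4 arrays. Of 254 groups tested, 25 passed, where chance gives about 1 in 20 (12.7), and 20 of the 25 concerned NaPB replicate 4.

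NaPB replicate 4 lay far from the other NaPB arrays in drug-metabolizing genes: Cyp2b10 was at 77.7 (others 430 to 521), Gstm3 at 249 (758 to 899), Gsta1 at 41.0 (158 to 185), Gsta2 at 24.8 (69.1 to 83.0), Gstm1 at 435 (886 to 957), Cyp2c54 at 145 (312 to 357), Cyp2c39 at 14.7 (34.8 to 35.3), Aldh1a7 at 19.7 (54.2 to 60.8), Cbr3 at 0.319 (1.80 to 2.17) and Cyb5a at 139 (351 to 373). It also lay below them in Elovl6 at 0.973 (10.4 to 14.3), Sqle at 3.29 (13.1 to 14.4), Mcm10 at 0.727 (2.00 to 2.26) and Gapdh at 197 (375 to 379). The geometric mean over the members of a list was 13.5 for glutathione S-transferase genes (32.5 to 36.4), 2.86 for glucuronosyltransferase and sulfotransferase genes (8.01 to 9.49), 1.99 for Nrf2 targets (5.99 to 7.10), 1.75 for cholesterol synthesis (8.13 to 8.76), 4.19 for bile acid synthesis (8.35 to 8.98) and 134 for acute phase and complement genes (lowest of the others 31.0). Bright genes as a whole lay lower on this array (median log2 gap −0.89 over 1033 genes, −0.08 after quantile normalization). Departures such as that of Gapdh are therefore not particular to the gene. The members' median gap went from −0.99 to −0.34 with that normalization for bile acid synthesis, and from −2.33 to −1.86 for cholesterol synthesis. Other arrays far from their group were control replicate 1 in Hsd3b5 at 22.6 (16.0 to 16.9) and in Mki67 at 0.41 (0.929 to 1.07), control replicate 2 in Rrm2 at 0.0413 (0.135 to 0.151) and in Ephx1 at 31.5 (50.0 to 53.6), and NaPB replicate 1 in the p53 list at 0.900 (0.680 to 0.712). Among features without a gene name, which the gene comparison does not use, 369 of 31511 differed between the diets (98 higher, 271 lower; limma adjusted p below 0.05).

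A compressed range left by the scaling of NaPB replicate 4 would lower bright genes alike: its median log2 gap to the other NaPB arrays over 1033 bright genes was −0.89, and −0.08 after quantile normalization. After that normalization 21 of 26 acute phase members were still highest of the 8 arrays there and 17 of 19 members of the list of CAR and PXR target P450 genes lowest of the NaPB arrays, which argues against compression as the whole cause. The median log2 gap of these P450 members went from −1.73 to −0.94 with it, so part of their gap went with the range of the array. A control liver with a treated label is argued against by Cyp2b10, 14.9 times its highest control value there. An acute phase response that lowered P450 transcripts in that liver may account for both sides of the pattern, but it cannot be told apart from other differences of a single sample; 9 of 30 other P450 genes were lowest of the 8 arrays there after quantile normalization.

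S100a8 was 86.5-fold higher on the NaPB diet. The other 9 neutrophil markers had a median log2 fold change of 0.33 (median absolute deviation 0.60, scaled to estimate an SD). They include granule genes that mature neutrophils in tissue need not transcribe, so this median alone does not weigh against neutrophils in the NaPB livers. Such cells would bring S100a9, the usual partner of S100a8. S100a9 was at 2.76, 1.19, 1.41 and 6.63 on NaPB replicates 1 to 4 against at most 2.00 on the control arrays, while Retnlg, at most 0.586 there, reached 6.69 on NaPB replicate 2, where S100a8 was highest. S100a9 did not follow S100a8 on NaPB replicates 1 to 3, which argues against neutrophils as the source of the whole rise. A smaller share of them in single livers stays open. Signal of another transcript on the S100a8 feature could give such a rise and stays open, since 1 feature names the gene; no other biological explanation was tested.

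Genes called lower often rested on features that other features of the gene did not share, and 24 of the 128 were chemosensory receptor genes, a class chosen after the data were seen (18.8%, against 9.88% of the genes called higher and 6.73% of tested genes), so this share is a description and no test. A general shift of dim features would move this class as a whole, but the median log2 fold change of all 1395 such genes was −0.036. This argues against a shift of the whole class and not against a shift of part of it. Genes at the floor on both diets cannot show a shift. A difference between single features that follows the diets and not the transcript is a candidate explanation for part of the calls: after centring each gene with at least 8 features per array, 51 features differed between the diets, and none did in the other 34 splits (highest 0). The labels name no slide or print batch, so a batch that goes with the diets cannot be told apart from diet.

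Of the 35 splits of the 8 arrays, 1, the real one, gave as many called genes (209, highest of the others 1). The same held for genes higher (81 against 1) and lower (128 against 1), which argues against chance for these counts. Chance is not excluded, since first of 35 is the most that the splits can show. They also take the arrays as separate samples, which no label states. For the number of lists called the splits do not argue against chance. A split has no direction of its own, and the larger of its 2 directions was counted for each split but the real one. In this way 15 splits gave at least 9 lists (the 9 higher, highest of the others 17), which points to a structure shared by genes across the arrays. For the 2 lower, 33 splits gave at least 2 (highest 17). That count sets the smaller direction of the real split against the larger direction of every other split, so it decides nothing. By permutation of the arrays, taking each list by itself, the real split gave the smallest camera p for the CAR and PXR target P450 genes (1 split; p = 6.79e-26, smallest of the others 5.19e-14), the female-biased genes (1; 1.03e-15, 1.03e-07) and the Kupffer cell and macrophage markers (1; 0.000217, 0.000848). Over all 38 lists this does not exclude chance by itself, since the real split was first for 3 lists and another split for 5 (1.09 expected); the p of the Kupffer cell list lies close to that of the next split. Chance is not excluded for the camera result of the lists of glutathione S-transferase genes (2 splits: 6.76e-09, 5.73e-09), glucuronosyltransferase and sulfotransferase genes (5: 7.11e-07, 2.35e-10), other drug-metabolizing genes (10: 0.00075, 2.00e-09), Nrf2 targets (15: 0.0085, 3.50e-09), S phase (4: 0.000329, 9.17e-05), mitosis (9: 0.00167, 1.91e-07), male-biased genes (6: 6.92e-06, 3.33e-08) and ribosomal protein genes (16: 0.00344, 5.34e-11). This concerns the lists and not their single members. Gstm3, Gsta1, Gsta2 and Gstm1 were called by limma in all 8 fits with 1 array left out.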

How the results depend on the processing

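The settings that leave out control replicate 1 with NaPB replicate 4, or join quantile normalization with leaving out NaPB replicate 4, were chosen after the data were seen; the others were planned. Of the 209 called genes, 179 were also called with quantile normalization, 110 with arrays shifted to the same median, and 83 without NaPB replicate 1, the fewest of the fits without 1 array. The median log2 fold change of all genes moved by less than 0.1. The number of called genes ran from 88 to 365 when 1 array was left out (36 to 211 higher, 48 to 154 lower, the same numbers at 2-fold), and the lists called from 7 to 10 higher and from 2 to 7 lower. Quantile normalization called 328 genes, 228 lower (203 by 2-fold), and 5 lists lower. Shifting each array to the same median called 111 (46 higher, 65 lower, all by 2-fold). Array weights called 812: 458 higher (428 by 2-fold) and 354 lower (314). Leaving out control replicate 1 with NaPB replicate 4 called 570 (374 higher, 196 lower, all by 2-fold) and 1 list lower. Quantile normalization without NaPB replicate 4 called 607: 291 higher (235 by 2-fold) and 316 lower (245), with 5 lists lower, and reversed the acute phase list to lower (adjusted p = 0.0107). All features tested singly gave 643 (207 higher, 436 lower, all by 2-fold). A Welch test per gene in place of limma called 3 (1 higher, 2 lower, all by 2-fold; 1821 at an unadjusted p below 0.05). Thresholds of 0.01 and 0.1 gave 58 and 364 genes. With log2(value + 1), 29 genes were called and 2-fold higher and 37 lower. Both filters on dim genes called 5 lists lower. The filter at the median called 6 lists higher in place of 9, losing glucuronosyltransferase and sulfotransferase genes (adjusted p = 0.0917), Nrf2 targets (0.172), S phase (0.149) and mitosis (0.0691) and gaining neutrophil markers (0.0445), and array weights ended the mitosis call (0.078). An estimated correlation called 0 lists in either direction, and fry called 2 higher and 1 lower. Fewer arrays or fewer genes tested are part of the settings that leave some out; for the rest the cause was not tested. Signal close to the floor limits what can be said of dim genes: 171 of the 209 called genes lay above the first quartile of mean intensity and 116 above the median.

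The replicate numbers showed no regular pairing of the arrays: residual correlations of arrays with the same number were 0.23, −0.29, 0.04 and 0.23. Among the control arrays, only replicate 4 correlated best with the NaPB array of its own number. Pairing was not tested. With the number as a block, 135 genes were called, 77 of them lower (77 by 2-fold).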

Other observations

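The tests of the female-biased genes and the choice of bright genes below were made after the results were seen. Of the called genes with a mean log2 intensity above 2, 24 were higher and 12 lower on the NaPB diet, and 17 of the 36 stood in none of the gene lists. Among these, Gm10639 (log2 fold change 3.68), Tnfrsf11a, the gene of the receptor RANK (2.61), the keratin gene Krt31 (1.89) and the major urinary protein pseudogene Mup-ps21 (1.83) were higher. The BMP antagonist gene Nog (−2.85), Gml2 (−2.17), Saraf, a regulator of store-operated calcium entry (−1.87), and Enho, which encodes adropin (−1.56, with −1.44 at its other feature), were lower. Pvalb (−1.91) and Lrrc2 (−1.47) were called lower by their brightest feature, while their other features gave 0.11 and 0.06.

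Some genes of growth, lipid and heme synthesis, chosen after their values were seen, lay above the control range on NaPB replicates 1 to 3 and below it on NaPB replicate 4. Jun was at 14.0, 26.5, 11.9 and 3.40 on NaPB replicates 1 to 4 against 3.61 to 5.55 on the control arrays, Thrsp at 47.2, 55.0, 36.6 and 5.01 against 9.30 to 14.9, and Alas1, of heme synthesis, at 106, 194, 122 and 10.5 against 11.4 to 40.7. None of these passed with all arrays. The values are without quantile normalization, and bright genes as a whole lay lower on NaPB replicate 4 than on the other NaPB arrays. Their median log2 gap was −0.89, and −0.08 after that normalization. The small distance of Jun and Alas1 below the lowest control can therefore not be told apart from the range of this array.

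The rise of female-biased genes may reach beyond the P450 genes that CAR and PXR also target. The 10 members outside that list had a median log2 fold change of 1.27, 8 of them were above 0 and 3 were called (Prom1, Sult2a1 and Sult3a1). Camera gave p = 1.09e-06 for them, the smallest in a permutation over the 35 splits (1 split, the real one; smallest of the others 0.000515). This rests largely on the 3 called members, whose rise was already known, and the others had limma adjusted p between 0.313 and 0.798, so it is no independent evidence. Sulfotransferase genes are themselves induced by CAR, so the data do not separate a change in sex-biased expression from induction of single members.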
